A study of Homo sapiens with 6 samples.

How the data were processed

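Gene expression was measured in 6 samples of cells labelled HepG2, a human liver cancer line derived from a hepatoblastoma that is known to secrete albumin and alpha-fetoprotein. Per the labels' protocols, the cells were infected with an empty virus or with a virus carrying a short hairpin RNA against SOX9, so as to make a knockdown clone and a control clone. Per the labels' protocols, total RNA was checked for integrity, purified with DNase treatment, amplified from the 3' end, labelled with biotin and hybridised to Affymetrix arrays. The 3 samples of each group were grouped by their titles, which also number the replicates. The free-text description of the 3 knockdown samples names the empty virus, against their titles, sources and genotypes. No label says that the replicates were separate cultures, so p-values measure the spread between these samples only, which may be technical.

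The authors deposited log2 values for 49372 probe sets, computed with RMA and the affy package, per the submitters' processing notes, which give no versions. RMA corrects background, normalises between arrays and summarises the probes of a set, so the values are log2 intensities on one scale for the 6 arrays. The array medians lay between 5.426 and 5.484. The deposited tables, one with probe annotation and one without, were compared value by value, and their largest difference was 0. The annotated table names no genome build. Its contig names follow the style of hg19 (GRCh37), and positions are given here as that table gives them. Which exon or untranslated region a probe set covers was not analysed here.

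Of the probe sets, 46236 named 1 gene, 2517 named several, 540 named none and 79 were control probe sets. Gene names were updated through the gene identifier with a RefSeq gene table of GRCh38.p14, which held 18401 of the 18574 identifiers and changed 1470 symbols. None of that table's coordinates were used. For each gene the probe set with the highest mean over the 6 arrays was taken among those naming 1 gene, which left 18574 genes. No filter on dim genes was applied. The number of arrays, 3 per group, limits the precision.

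Knockdown and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior) on the log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A second count required a change of at least 2-fold. All fold changes are knockdown over control. Gene lists, 41 in number, were written down with the tests, the alternatives and the rule for named genes before the data were examined. They cover SOX9 targets, liver and bile duct identity, stem cell markers, signalling pathways, cell cycle, stress responses, metabolism and markers of other cell types. Each list was tested against all other genes with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. The same test was run on the gene ontology and pathway terms that the deposited table attaches to its probe sets (15 to 300 genes per term) and on chromosome arms with at least 20 genes. Single measures of RNA quality were compared with a two-sided exact permutation test, for which 3 against 3 arrays allow no p under 0.1.

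The genes named in the text are SOX9; the 12 of largest rise and the 12 of largest fall among genes past the threshold whose groups did not overlap, whose higher group lay above the median gene and whose symbols are approved names; up to 4 members per direction of each list by size of change among those past the threshold, or the 2 of smallest p where none passed; and 16 genes fixed by name (SOX4, AFP, ALB, HNF4A, EPCAM, KRT19, PROM1, CD44, CTNNB1, AXIN2, MYC, CCND1, CDKN1A, CDH1, VIM and MKI67). Some list members that this rule picks are not reported here. Any other gene named was chosen after its values were seen, and the text says so.

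The steps were tested on simulated data for the comparison of knockdown with control, run on 18574 genes. Of these, 200 were changed by 0.5 to 2 on the log2 scale, and a list of 30 others was moved by 0.4. The fit recovered 48% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 1.5 or 2. Of its 196 calls, which include those on the moved list, 13 were on unchanged genes (6.63%). Far fewer genes were changed than the 3113 called in the data, and the noise was independent between genes. These rates therefore need not hold for the real comparison. Alternatives were repeated scaling between arrays, filters on dim genes, other ways to choose probe sets, other variance models, the replicate number as a block, leaving out each array in turn, and other gene set tests. Probe sets naming several genes or none entered no gene-level comparison.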

Results

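The data comprised 6 arrays, 3 of cells labelled HepG2 infected with an empty virus and 3 of cells labelled HepG2 carrying a hairpin RNA against SOX9, a transcription factor of cartilage, bile duct and progenitor cells. Per the series' design text, the aim was to find the cellular pathways that change when SOX9 is knocked down. Each array gave a log2 value for 49372 probe sets, from which 18574 genes were compared. Pearson correlations across genes lay between 0.9945 and 0.997 within groups and between 0.9852 and 0.9926 across groups, where genes are not independent replicates. The first principal component held 62.3% of the variance and separated the groups. Control replicate 3 lay closest to the knockdown arrays on it, at -10.5, against -23.4 and -30 for the other control arrays and 17.3 to 23.4 for the knockdown arrays.

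SOX9 itself was the first item compared, since it checks the labels. SOX9, by its probe set of highest signal, was lower on every knockdown array than on every control array. This probe set read 7.94 ± 0.25 (SD, n = 3) in control and 6.96 ± 0.11 (SD, n = 3) in knockdown arrays. The difference was -0.97 on the log2 scale (SE 0.13, 95% confidence interval -1.26 to -0.68, limma adjusted p = 0.00114), which left 51.0% of the control level. It aligns to chromosome 17, 70121763 to 70122557, in the deposited table. The other SOX9 probe sets, aligned to 70117170 to 70122557, differed by -0.83 (adjusted p = 0.0047 over all probe sets) and by -0.81 (adjusted p = 0.0716, not past the test). The last of these is the SOX9 probe set left when names ending in _x_at or _s_at are excluded, and the gene then missed the threshold (adjusted p = 0.0569).

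**Figure D1:**
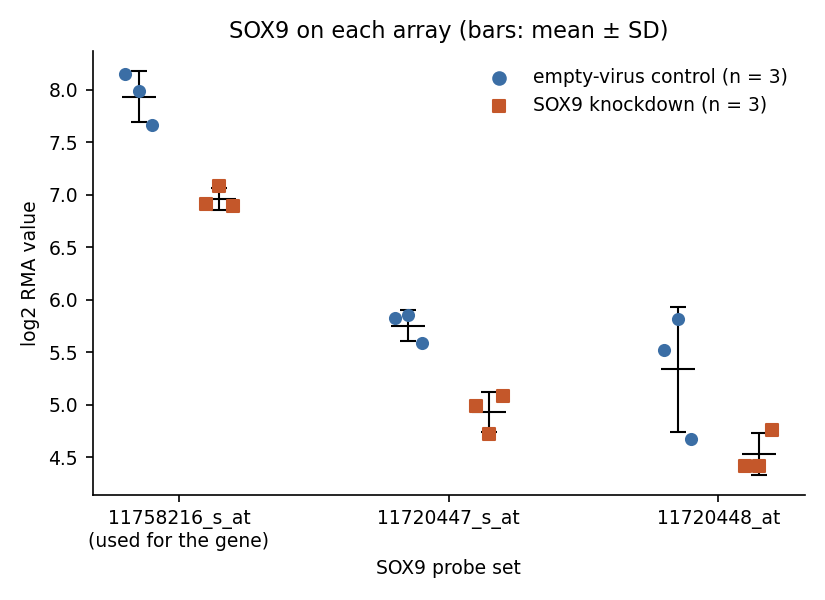
Log2 RMA values of the 3 SOX9 probe sets on each array, with circles for empty-virus control, squares for SOX9 knockdown, and bars for the mean ± SD of 3 arrays. The knockdown arrays lie below all control arrays for 2 of the probe sets, and for the third, whose name ends in _at alone, the values overlap.

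The comparison of all genes asked which transcripts differ between the knockdown and control clones. The largest rises included DKK1, a secreted inhibitor of Wnt signalling, RSPO3, a secreted enhancer of Wnt signalling, and SPINK1, a secreted trypsin inhibitor. The largest falls included ARRDC4, an arrestin family member induced by glucose, ASNS, which makes asparagine, and CBS, an enzyme of homocysteine metabolism. DKK1 went from 7.20 ± 0.08 to 9.15 ± 0.09 (SD, n = 3 per group), a 3.87-fold rise (log2 1.95, SE 0.10, limma adjusted p = 8.5e-06). ARRDC4 went from 9.79 ± 0.31 to 6.94 ± 0.06 (SD, n = 3 per group), a 7.25-fold fall (log2 -2.86, SE 0.14, adjusted p = 8.7e-06). The DKK1 probe set aligns to chromosome 10, 54073968 to 54077678, and that of ARRDC4 to chromosome 15, 98516602 to 98517067.

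Among the other genes of largest rise, SPINK1 rose 3.89-fold, RSPO3 3.60-fold, UBASH3B 3.42-fold, ELAPOR1 3.27-fold, RBPMS2 3.19-fold, PHF19 3.04-fold, STS 2.95-fold and PTGES 2.89-fold. EMP3 rose 2.84-fold, GPRC5A 2.83-fold and KRT8, an epithelial keratin, 2.75-fold. Among the other genes of largest fall, SORBS2 fell 6.12-fold, NIBAN1 6.04-fold, CBS 5.43-fold, ASNS 5.15-fold, LGSN 4.16-fold, SLC12A1 4.14-fold and ZMAT1 3.99-fold. SMC1B fell 3.97-fold, PCSK1, a prohormone convertase, 3.79-fold, TSC22D3, a glucocorticoid-induced gene, 3.69-fold and PCDH1 3.66-fold. The limma adjusted p of these 24 genes was at most 0.000864. Not all probe sets of some genes were called in the same direction: 2 of 5 were for ELAPOR1, 1 of 2 for RBPMS2 and 1 of 3 for PHF19. For PCDH1 2 of 4 were, for STS and SLC12A1 3 of 4 each and for SORBS2 9 of 11. For the other genes all were. In total 3113 of 18574 genes changed (16.8%), 1563 higher and 1550 lower. Of these, 254 changed at least 2-fold, 89 higher and 165 lower. The 3 arrays of one group lay on one side of the other 3 for 32.4% of genes, where chance gives 10%. The number of changed genes was 1967 without control replicate 1 (898 higher, 1069 lower) and 1773 without SOX9 knockdown replicate 1 (817 higher, 956 lower), and centring on housekeeping genes turned the split to 1168 higher and 1952 lower (61 and 194 at least 2-fold). Changes of at least 2-fold were 145 higher and 213 lower without control replicate 3, 53 and 120 with the mean of all probe sets of a gene, and 65 and 85 with the lowest 60% of genes left out.

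**Figure D2:**
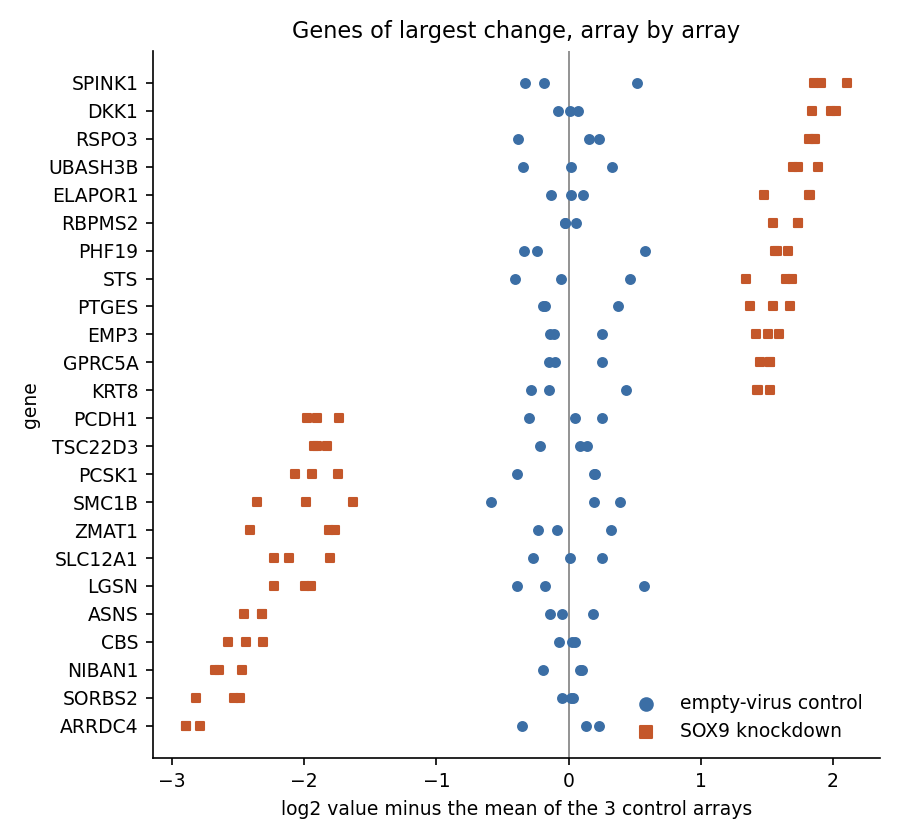
Log2 value minus the mean of the 3 control arrays for the 12 named genes of largest rise and the 12 of largest fall, one point per array (circles, empty-virus control; squares, SOX9 knockdown). The groups do not overlap for any of the 24 genes, and ARRDC4 lies farthest from control, at a mean of -2.86.

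Of the 41 gene lists, 5 were lower as a group in knockdown cells and 5 were higher. With an estimated correlation 1 of these 10 calls held, and another split of the same arrays gave 9 lists. Camera on ranks gave 9 lists, and fry, which tests a list against no change, gave 10 (6 higher, 4 lower). The fry calls included p53 targets and housekeeping genes (fry adjusted p = 0.0413 for each), which did not pass camera. The falls of smallest camera p were in a mixed list of ER stress genes and targets of ATF4, the transcription factor of the amino acid and integrated stress responses, and in genes induced by hypoxia. In the list of ER stress and ATF4 genes, 23 of 37 members fell, 3 rose and 11 did not pass the test (25 and 3 adjusted over the list alone). Those that fell included ASNS (log2 fold change -2.36), DDIT3, which encodes the stress factor CHOP (-1.87), PHGDH, the first enzyme of serine synthesis (-1.32), and NUPR1 (-1.32). The 3 that rose were ATF5 (0.87) and the ER proteins SDF2L1 (0.69) and CRELD2 (0.48), of which SDF2L1 and CRELD2 missed the threshold without SOX9 knockdown replicate 1 (adjusted p = 0.0527 and 0.053). As a mean of its 2 probe sets CRELD2 differed by 0.24 (adjusted p = 0.158). The list median was -0.45 (camera adjusted p = 2.38e-11), and this call, alone among the 10, held with an estimated correlation (adjusted p = 0.0452). The correlation estimated for this list was -0.004, under the preset 0.01, yet its unadjusted camera p rose from 6.32e-13 to 0.0011. This rise therefore did not come from correlation among its genes. For lists with a higher estimate, the share due to correlation was not worked out. A call lost under this setting, for lists or terms, therefore does not show that correlation among genes undid it.

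Among hypoxia genes, 19 of 28 members fell and 9 did not pass the test (20 lower adjusted over the list alone). Those that fell included MXI1, an antagonist of MYC (log2 fold change -1.53), BNIP3L, a mitophagy receptor (-1.25), CA9, a carbonic anhydrase (-1.20), and PPP1R3C, a glycogen-targeting subunit (-1.16). The median was -0.63 (camera adjusted p = 2.38e-11), and the adjusted p was 0.44 with an estimated correlation. Of 6 replication-dependent histone genes measured, 4 fell (4 adjusted over the list alone), among them H2AC6 (-1.37) and H2BC5 (-1.09). The camera adjusted p was 0.000192, or 0.453 with an estimated correlation. The RNA was amplified from the 3' end, and which transcript forms of these histone genes were read was not tested. The fall therefore need not hold for all their transcripts. In fatty acid oxidation 6 of 24 members fell (6 adjusted over the list alone), including PDK4 (-0.69) and ECI1 (-0.57), with an adjusted p of 0.0332 and, with an estimated correlation, an adjusted p of 0.874. Among immediate early genes 8 of 30 fell and 2 rose (8 and 2 adjusted over the list alone). KLF10 (-1.17), KLF4 (-0.83) and ATF3 (-0.72) fell and FOSL1 (0.74) rose, with an adjusted p of 0.0358 and, with an estimated correlation, an adjusted p of 0.453. Leaving out control replicate 2 ended the calls of the fatty acid oxidation and immediate early lists (adjusted p = 0.0625 and 0.13), as did leaving out SOX9 knockdown replicate 3 (0.0651 and 0.0874), and leaving out control replicate 3 ended the first (0.104). The fatty acid oxidation call also ended with array weights (0.0931) and ranks (0.074), and the immediate early call under 6 further alternatives in scaling, filter, probe sets, weights and shared members (0.051 to 0.31). By fry, which tests a list against no change, the immediate early list had an adjusted p of 0.0546.

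The lists that rose held chaperones, ribosome biogenesis factors and mitotic genes. The ACTB 3' minus 5' difference, a sign of RNA quality, did not overlap between the same groups (2.51 to 2.56 in control and 2.19 to 2.34 in knockdown arrays, exact p = 0.1), here as for the lists that fell. That of GAPDH moved the other way, from a mean of 0.107 in control to 0.345 in knockdown arrays, with overlapping ranges. Among heat shock genes 11 of 15 members rose (14 adjusted over the list alone). The cochaperones DNAJA1 and FKBP4 rose by 1.43 and 1.14 on the log2 scale, the chaperone HSP90AA1 by 1.11 and its partner STIP1 by 0.87. The HSP90AA1 probe set aligns to chromosome 11, 27910458 to 27910995, whereas the band given for the gene is chr14q32.33. Which sequence it reads was not tested, and 2 of the 2 probe sets naming this gene were called higher. The median was 0.71 (camera adjusted p = 3.37e-11), and the adjusted p was 0.106 with an estimated correlation. In the list of MYC and ribosome biogenesis genes 17 of 27 members rose and 1 fell (18 and 1 adjusted over the list alone). POLR1A, the largest subunit of RNA polymerase I, rose by 0.83, PA2G4 by 0.74, PES1 by 0.71 and NOP2 by 0.71. The member that fell was MYC itself (-0.67, SE 0.14, adjusted p = 0.00807). The list had a camera adjusted p of 2.71e-08 and, with an estimated correlation, an adjusted p of 0.0534. The correlation estimated for it was -0.021, also under the preset 0.01.

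Of 39 genes of the G2 and M phases, 16 rose (20 adjusted over the list alone), among them KIF20A (1.12), BIRC5 (0.90) and CDC20 (0.78), with a camera adjusted p of 5.3e-08 and, with an estimated correlation, an adjusted p of 0.648. Control replicate 3 had the highest control mean for this list, 9.25 against 9.07 on both other control arrays, and the knockdown arrays lay between 9.46 and 9.53. The proliferation marker MKI67 differed by 0.51 (SE 0.17, adjusted p = 0.0725) and passed the test without control replicate 3 (0.73, adjusted p = 0.00413). It also passed with the lowest 40% or 60% of genes left out, an intensity trend, array weights or the replicate block (adjusted p from 0.0185 to 0.0494). Genes of the G1 and S phases did not shift as a list (6 of 40 higher, 3 lower, 7 and 4 adjusted over the list alone). In cholesterol synthesis 8 of 24 members rose and 1 fell (16 and 3 adjusted over the list alone). NSDHL rose by 0.96, EBP by 0.85 and ACAT2 by 0.81. The adjusted p was 0.00108, or 0.973 with an estimated correlation, and 0.131 with the fry test, which asks whether the list differs from no change instead of from other genes. Among NRF2 targets 6 of 26 rose and 1 fell (13 and 2 adjusted over the list alone), with GCLC, of glutathione synthesis, at 0.98 and the cystine transporter SLC7A11 at -0.45. The adjusted p was 0.000651 and, with an estimated correlation, an adjusted p of 0.839. Without SOX9 knockdown replicate 1, SLC7A11 missed the threshold (adjusted p = 0.0577).

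**Figure D3:**
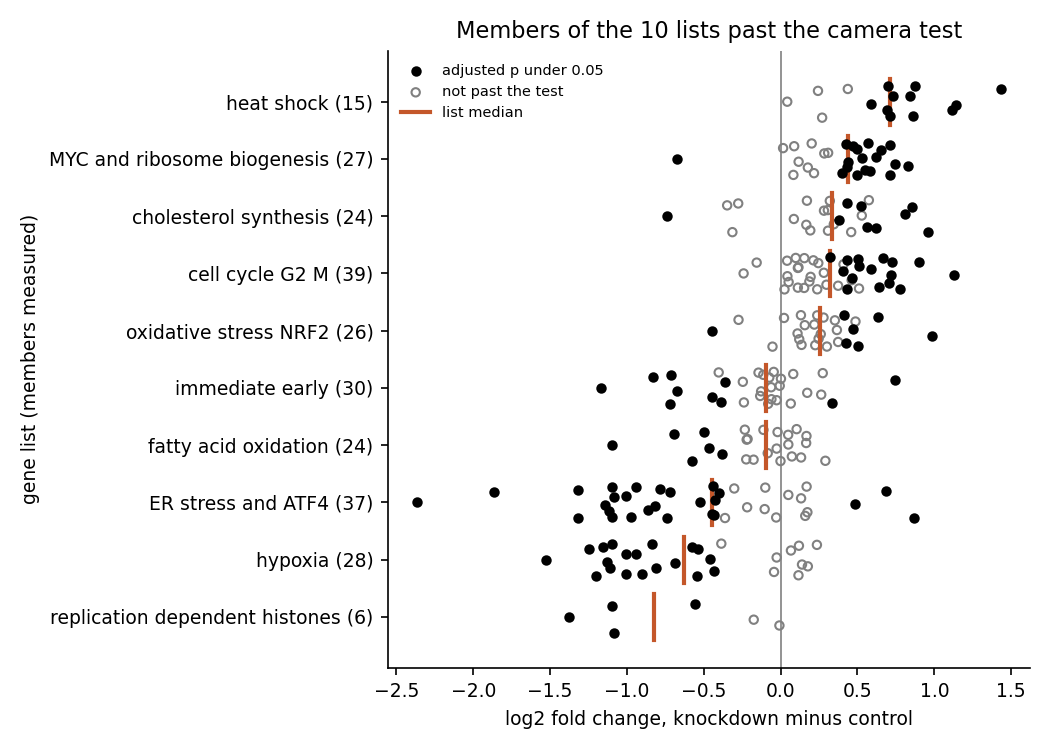
Log2 fold change, knockdown minus control, of each measured member of the 10 lists past the camera test (filled, adjusted p under 0.05; open, not past the test; bar, list median). The medians run from -0.82 for replication-dependent histones to 0.71 for heat shock genes.

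The lists closest to SOX9's known roles did not shift as groups, but many of their members were of low signal. At or under the median gene over the 6 arrays lay 10 of 13 SOX family and 17 of 18 cartilage genes. The same held for 12 of 22 stem cell markers and 12 of 20 biliary and progenitor genes. No detection level was measured, so changes in such genes may have been missed. In the SOX family 2 of 13 members fell, SOX6 (-0.83) and SOX4 (-0.44), and in the cartilage list SOX6 and the collagen gene COL9A3 (-0.48) fell among 18 (2 lower in each, adjusted over the list alone). The SOX4 call (adjusted p = 0.0251) ended without any 1 of 5 arrays, all but control replicate 2 (highest adjusted p = 0.0997), as a mean of its probe sets (0.188) and with the replicate block (0.0552). The SOX6 change was -0.19 (adjusted p = 0.2) as a mean of its 6 probe sets. Of 22 liver cancer stem cell markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone). CD44, a hyaluronan receptor, rose by 0.49 (adjusted p = 0.00889, or 0.0935 as a mean of its 10 probe sets), and MYC and KLF4 fell. PROM1 (0.04) and EPCAM (0.23) did not pass the test. No member of the biliary and progenitor list passed it in either direction by limma, with 3 of 20 at an unadjusted p under 0.05. Of its members, ONECUT2 differed by -0.23 (adjusted p = 0.118, but -0.35 and 0.0157 as a mean of its probe sets, and 0.0357 with the lowest 60% of genes left out) and KRT19 by 0.23 (adjusted p = 0.181).

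Among Wnt targets 4 of 26 rose and 2 fell (4 and 2 adjusted over the list alone), with DKK1, CCND1 (cyclin D1, 0.92, adjusted p = 0.000277) and BMP4 (0.84) higher and MYC lower. AXIN2, a general target of the pathway, differed by 0.19 (adjusted p = 0.256). The beta-catenin gene CTNNB1 differed by 0.48 (adjusted p = 0.152, or 0.0409 with array weights), and 1 of its 8 probe sets had that sign. Among Notch targets HES4 (-0.83) and HEY1 (-0.58) fell and 1 of 16 members rose (2 and 1 adjusted over the list alone). CDKN1A (-0.23, adjusted p = 0.142), CDH1 (-0.02, adjusted p = 0.962) and VIM (0.04, adjusted p = 0.856) did not pass the test. The camera adjusted p of these 7 lists, G1 and S phases included, was at least 0.657.

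Hepatocyte transcripts were low in both groups. In the control arrays 36 of 38 genes of the hepatocyte list lay at or under the median gene (6.12). ALB read 3.14 ± 0.44 in control and 3.37 ± 0.26 in knockdown arrays, and AFP 2.70 ± 0.14 and 2.61 ± 0.11 (SD, n = 3 per group). All 23 probe sets of ALB, AFP, APOA1, SERPINA1, APOB and FGB, of which APOA1, SERPINA1, APOB and FGB were chosen after their values were seen, lay at or under the median probe set of the control arrays. The 2 hepatocyte genes above the median gene were CPS1, a urea cycle enzyme, at 12.1 ± 0.20 and PCK1 at 6.30 ± 0.19 in control arrays (SD, n = 3). The list did not shift with the knockdown (camera adjusted p = 0.895). In it 4 genes rose and 2 fell (4 and 2 adjusted over the list alone), with RBP4 (1.26) and FOXA1 (0.80) higher and PCK1, of gluconeogenesis, lower (-1.41). The other that fell, CPS1 (-0.41, adjusted p = 0.0414), missed the threshold without any 1 of 5 arrays, all but control replicate 3 (0.0539 to 0.137), with arrays centred on their medians (0.0558) and with the replicate block (0.0934). HNF4A, a liver transcription factor, rose by 0.54 (adjusted p = 0.025), a call that ended without control replicate 1 (0.0709) or 2 (0.0742) or SOX9 knockdown replicate 1 (0.109) or 2 (0.0786). The HNF4A change was 0.26 (adjusted p = 0.132) as a mean of its probe sets and 0.11 (adjusted p = 0.607) without probe sets ending in _x_at or _s_at. Of 12 genes of fetal liver and hepatoma, AKR1B10 alone passed the test (0.64), and 2 rose and 2 fell adjusted over the list alone. AKR1B10 read 3.67 in control and 4.31 in knockdown arrays, under the median gene, and its detection was not tested.

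**Figure D4:**
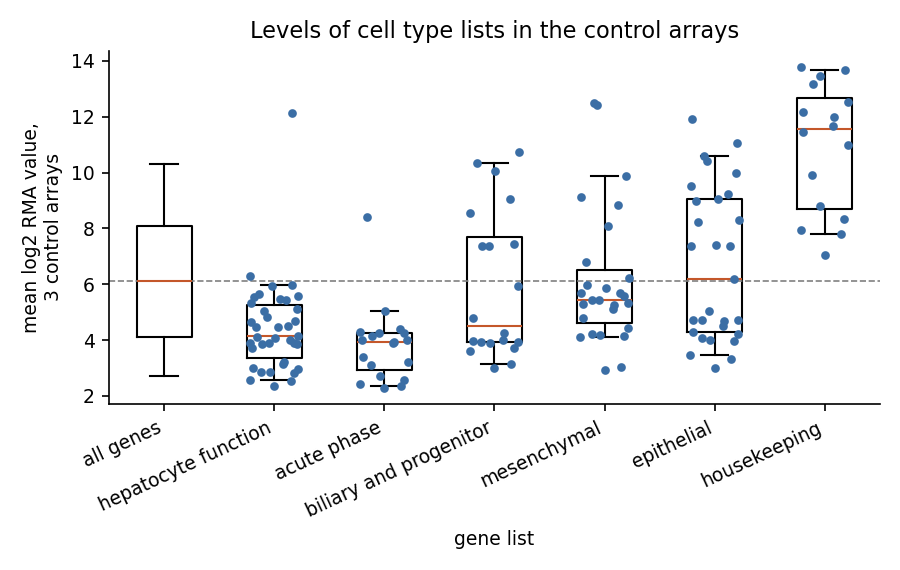
Mean log2 RMA value over the 3 control arrays for all genes and for the members of 6 lists (points, genes; boxes, quartiles with the median; whiskers, 5th and 95th percentiles; dashed line, median of all genes). Of 38 hepatocyte genes 36 lie at or under the line, whereas all 16 housekeeping genes lie above it.

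Annotation terms were tested beside the lists. Of 2106 terms tested with camera, 46 were higher and 5 lower. The terms of smallest p were led by the proteasome, the complex that degrades ubiquitin-tagged proteins, and by messenger RNA splicing. In the proteasome accessory complex 11 of 17 genes rose (median 0.47, camera adjusted p = 5.36e-05), and in splicing via the spliceosome 51 of 163 genes rose and 6 fell (median 0.19, adjusted p = 0.00014). The terms of autophagic vacuole assembly (9 of 30 genes lower, median -0.22, adjusted p = 0.0049) and mitochondrial fatty acid beta-oxidation (5 of 17 lower, median -0.22, adjusted p = 0.0049) were lower. With an estimated correlation no term passed camera, with 32 at an unadjusted p under 0.05, and the adjusted p of each of these 4 terms was 0.999. Another split of the same arrays gave 56 terms.

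Chromosome arms were compared because the knockdown and control cells are separate clones. None of 41 arms shifted by camera (smallest adjusted p = 0.284), with 6 at an unadjusted p under 0.05. Arm medians lay between -0.054 and 0.076. With an estimated correlation none passed either, with 2 at an unadjusted p under 0.05. With the lowest 60% of genes left out, 1 arm passed.

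RNA quality and labelling were measured with control probe sets. The 3' minus 5' difference of the ACTB control probe sets was 2.54 ± 0.03 in control and 2.27 ± 0.08 in knockdown arrays (SD, n = 3 per group, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). That of GAPDH was 0.107 ± 0.129 and 0.345 ± 0.094 (exact p = 0.2), with overlapping ranges, and so moved the other way. Both ACTB control probe sets read higher in knockdown arrays, by 0.54 (3') and 0.807 (5'). A change in ACTB expression cannot be told apart here from a difference in RNA quality. Spiked-in poly-A RNAs read 6.50 and 6.66 on control replicates 1 and 2, 7.12 on control replicate 3 and 6.94 to 7.30 on the knockdown arrays (exact p = 0.2).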

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

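The counts over other splits of the 6 arrays were planned before the results were seen, and the other tests of this part were chosen after the results they address had been seen. Chance could not be tested to a share under 0.05 by regrouping, because 3 against 3 arrays make 10 splits. The real split gave 3113 changed genes and the highest of the other splits 0 by limma, where 1 of the 10 splits, the real one, was as large. For genes changed at least 2-fold these values were 254 and 0, with 1 split as large. For gene lists they were 10 and 9, again with 1 split as large, for annotation terms 51 and 56, with 2 splits as large, and for chromosome arms 0 and 13, with 10 splits as large. The 56 terms came from the split that sets control replicates 1 and 3 and SOX9 knockdown replicate 2 against the others.

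Signals also appeared in probe sets that the gene comparisons did not use. Of the 2517 probe sets that list several genes, 25 were higher and 26 lower at least 2-fold in knockdown arrays. Of the 540 probe sets that list no gene, 5 were lower at least 2-fold. Among the probe sets changed at least 2-fold, 5 list TXNIP, an arrestin related to ARRDC4 and like it induced by glucose, together with another gene. They fell by 2.97 to 3.08 on the log2 scale (limma, largest adjusted p = 8.77e-05), the lowest change being -3.085. Also among those changed at least 2-fold, 9 that list HSPA8 with other genes rose by 1.10 to 1.98. Another 5 that list HSPA1A and HSPA1B rose by 1.16 to 1.59. HSPA8, HSPA1A and HSPA1B are chaperone genes like those of the heat shock list. Probe sets listing these genes or TXNIP that changed less than 2-fold or missed the threshold were left out, so these ranges are bounded by that filter. The 3' control probe set of ACTB read 0.54 higher in knockdown arrays (13.3 against 12.8). These genes were chosen after their values were seen, and which listed gene gave the signal was not tested.

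Hepatocyte transcripts were low on all arrays, although the cells are labelled HepG2. A general failure of labelling or of the probe sets is argued against by genes of 7 lists that growing cells use, of which 3 of 203 lay at or under the median gene, compared with the 36 of 38 hepatocyte genes (Fisher exact p = 6.44e-37). Genes are not independent, and this comparison was chosen after the hepatocyte levels were seen, so the p overstates its weight. The knockdown is argued against as the cause, since those 36 genes were counted in the control arrays alone. Whether the cells were other than HepG2, or HepG2 cells that had lost their liver programme, stays open. Among the genes fixed by name, VIM of the mesenchymal list read 12.48 in control arrays. Of the epithelial list, CDH1 read 4.06, KRT19 3.95 and EPCAM 7.36. Above the median gene over the 6 arrays lay 8 of 27 mesenchymal and 15 of 29 epithelial genes. These levels were not compared with reference levels of HepG2. The highest percentile among ALB, AFP, APOA1, SERPINA1, APOB and FGB was 34.9 (APOA1), but 4 of these genes were chosen after their values were seen, levels of different probe sets also depend on how well they bind, and poor binding of hepatocyte probe sets in particular was not tested.

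Control replicate 3 lay toward the knockdown arrays. A knockdown sample labelled as control is argued against, because over 360 genes changed at least 2-fold without this array, with probe sets chosen over all 6 arrays (358 when chosen over the other 5), its median share of the way to the knockdown mean was 0.29 (quartiles 0.16 and 0.43). Knockdown cells or RNA mixed into it cannot be told apart from other sources of spread: 13.6% of these genes departed from one common share, and 14.9% did on control replicate 2, with shares of 0.45 for SOX9, 0.35 for ARRDC4 and -0.03 for CBS. Labelling or amplification shared with the knockdown samples stays open: its poly-A spikes read 7.124, within the 6.94 to 7.30 of the knockdown arrays, but its ACTB 3' minus 5' difference of 2.51 lay with the other controls (2.55 and 2.56) and outside the knockdown range (2.19 to 2.34). No biological explanation was tested.

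The ER stress and ATF4 list and the hypoxia list were lower and the heat shock, ribosome biogenesis and mitotic lists higher, of which the first alone held with an estimated correlation (adjusted p = 0.0452, against 0.0534 to 0.648 for the others). An offset of whole arrays is argued against, because it moves all genes of an array alike, whereas the lists moved in both directions. The smallest list median over 4 scalings, the deposited one among them, was 0.259 in size, in the direction reported. The lists were picked after their medians were seen. Scaling that depends on signal level stays open, since it was tried only by quantile normalization of values already normalised. A difference in culture between the clones, such as in medium, density or time of harvest, cannot be told apart from an effect of SOX9, since each group is 1 clone. The range of a list mean within a group was up to 48.9% of the difference between groups (mitotic genes), and 10.7% for the ER stress and ATF4 list. Whether a second hairpin against SOX9 moves these lists is not given in the sources used here.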

How the results depend on the processing

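Leaving out proteasome genes was chosen after seeing the data, and the other tests before. The deposited tables were identical, so exchanging them gave the same values. Leaving out 1 array at a time gave 1773 (SOX9 knockdown replicate 1) to 3562 changed genes (control replicate 3), 194 to 358 at least 2-fold, 8 to 10 lists, 41 to 66 terms, 0 arms, and for SOX9 -1.105 to -0.865 (largest adjusted p = 0.00795). Other scalings (quantile, array medians, housekeeping genes) gave 3120 to 3370 changed genes. Changed genes numbered 1231 (523 higher, 708 lower) with an unmoderated linear model, which has fewer degrees of freedom, and 6220 with every probe set tested by itself (656 at least 2-fold, 210 higher and 446 lower), which tests more features. Changes of at least 2-fold numbered 150 with the lowest 60% of genes left out and 124 (31 higher, 93 lower) with treat against a fold of 1.5. Fewer genes were tested in the first, and the second asks for more than a change. With an estimated correlation 1 list and 0 terms passed camera (32 terms at an unadjusted p under 0.05). With the lowest 60% of genes left out 1 arm passed, and without probe sets ending in _x_at or _s_at SOX9 was -0.806 (adjusted p = 0.0569, with a noisier probe set). The replicate number as a block gave 2179 changed genes, 254 at least 2-fold, 10 lists, 52 terms, 0 arms and SOX9 at -0.972 (adjusted p = 0.000598). The deviations of same-numbered arrays correlated at -0.198, -0.425 and -0.355, which gives no sign of pairing by number. Those of control replicates 1, 2 and 3 with SOX9 knockdown replicates 2, 3 and 1 correlated at 0.367, 0.496 and 0.272, and the remaining pairs at -0.193 to 0.12. Whether arrays share a factor across groups under other numbers was not tested. Without proteasome genes 36 terms passed. Sign changed for genes not past the test: VIM -0.016 (quantile normalization), and -0.022 with centring on housekeeping genes, where PROM1 was -0.023 and SERPINA1 -0.023; CDH1 0.003 (array medians); CTNNB1 -0.104 and APOB 0.009 (mean of probe sets); and, without probe sets ending in _x_at or _s_at, CTNNB1 -0.032, ALB -0.008 and FGB 0.037. Leaving out 1 array gave PROM1 -0.085 to 0.169, CDH1 -0.119 to 0.093, SERPINA1 -0.168 to 0.216, APOB -0.281 to 0.054 and FGB -0.159 to 0.037. For the 103 named genes over the alternatives, 1536 values kept their direction and side of the threshold, 28 lost and 9 gained the call, and 18 changed direction. Where no cause is named, the cause was not tested. Genes of low signal, such as ALB and AFP, may be limited by the signal of the array, and no detection level was measured.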

Other observations

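No test of an explanation is reported in this part, and its genes follow the rule for named genes. Epithelial and mesenchymal genes moved in both directions. Of 29 epithelial genes 3 rose and 4 fell (4 and 4 adjusted over the list alone), with KRT8 (1.46) and KRT18 (0.52), which pair in the keratin filaments of simple epithelia, higher and the tight junction gene CLDN7 lower (-1.84, limma adjusted p = 4.27e-05). Of 27 mesenchymal genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with S100A4 at 0.70 and, among transcription factors, TWIST2 at 0.60 (0.30, adjusted p = 0.309, without probe sets ending in _x_at or _s_at) and SNAI2 and TWIST1 at -1.26 and -1.07. Among YAP targets 5 of 25 rose and 4 fell (5 and 7 adjusted over the list alone), with CCN2 at 1.41, and among TGF-beta targets 2 of 20 rose and 4 fell (3 and 5 adjusted over the list alone). The camera adjusted p of each of these 4 lists was 0.99.

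Among p53 targets 9 of 31 rose and 4 fell (9 and 4 adjusted over the list alone), with PLK2 higher (1.13) and GDF15 (-1.15) and SESN2 (-1.14) lower. Among interferon response genes 3 of 41 rose and 6 fell (4 and 7 adjusted over the list alone), with ISG20 at -1.18 and IRF7 at -0.93. In glycolysis 3 of 25 rose and 6 fell (4 and 6 adjusted over the list alone), and in oxidative phosphorylation 2 of 43 rose (2 adjusted over the list alone). No gene of the acute phase list (19 measured) or the metallothionein list (11 measured) passed the test by limma, with 1 in each at an unadjusted p under 0.05. The camera adjusted p of these 6 lists was at least 0.627. By fry, which tests a list against no change, p53 targets had an adjusted p of 0.0413. Among genes of the G1 and S phases CCNE1 (0.81) and RRM2 (0.65) rose, but CCNE1 differed by 0.22 (adjusted p = 0.255) without probe sets ending in _x_at or _s_at. Of the markers of other cell types, 2 of 15 fibroblast genes rose and 1 fell, 1 of 14 endothelial genes fell, and 1 of 17 leukocyte genes and 1 of 16 kidney line genes rose, with camera adjusted p of at least 0.424.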
